A study of Danio rerio with 12 samples.

How the data were processed

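MicroRNAs were measured by small RNA sequencing of cells from transgenic zebrafish raised at 28 °C. Per the labels' protocols, cells were dissociated with Liberase, GFP-positive cells were collected by FACS, RNA was extracted with Trizol, and libraries were made with Illumina TruSeq. The submitters' processing notes name STAR 2.3.0 and the genome build Zv9, without their order or settings. The adapter trimming, microRNA annotation, counting program and any filter are not given in the sources used here. Groups, stages and replicate numbers were taken from the sample titles. The E1 and E2 marks in the titles differ from those in some deposited file names, and the titles were followed.

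Each library has a sense and an antisense table, with a line per genomic copy of a mature microRNA in Zv9, 1-based and inclusive. The deposited read counts are whole numbers of reads per genomic copy, and a read that maps to several copies is counted at each, as seen when their sum is set against the library total. The deposited expected counts, named multi-mapping-adjusted read counts per the file headers, divide such a read over its places and are not scaled to depth. Their sum was between 99.1% and 99.96% of the reads on mature microRNAs in each library. The deposited signal columns give read counts as RPM relative to 2 library totals, per the file headers, the reads on mature microRNAs and a larger total that the headers do not define. They served only to recover both totals, as read count over RPM. No Zv9 annotation was used, so exons, introns and host genes in Zv9 are not analysed here. In the gene table of GRCz12tu, 46 of the 47 named microRNAs matched by name, and no coordinate of that table is printed.

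Expected counts were summed over the copies of each mature microRNA and rounded, giving 326 microRNAs. Reads of near-identical microRNAs (let-7, miR-125, miR-430, miR-23, miR-27 and miR-133a members and the joint miR-126 5' arm entry) are uncertain between members. The identical files of replicate 1 at 72 hpf, titled Endo and NoEndo, were left out of every comparison, since the labels cannot say which population they belong to. MicroRNAs with at least 10 CPM in at least 3 libraries were tested, 265 in all, which held at least 99.9% of each library's counts. Shares and CPM describe levels relative to the library, not molecules per cell. Normalised CPM are scaled by TMM factors, which ran from 0.468 (Endo at 6 dpf) to 2.37 (NoEndo replicate 2 at 48 hpf).

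The test was edgeR's robust quasi-likelihood F test with TMM scaling and Benjamini-Hochberg adjustment at 0.05. Endo was compared with NoEndo with stage as a factor, and within each stage in a model with 1 mean per population and stage. Trends were slopes on log2 hours within each population, and their difference was tested in the same model. The SE is the log2 difference over the square root of F. The biological coefficient of variation was 0.450. Lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry, from 3 tested members on. The 6 lists that passed camera also passed fry with all libraries, as did the gut and liver, mesenchyme, endocrine and pancreas, eye and let-7 lists, and none passed with an estimated correlation. The list of other vascular microRNAs shares 8 tested members with the Hox list and 3 with the miR-17-92 list. Library measures were compared by exact two-sided permutation over all divisions of 5 against 5, without regard to stage.

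Comparisons, lists and alternatives were fixed before the data were examined, and so was the rule for named microRNAs. It takes, at a mean of at least 100 CPM, the 12 largest increases and 12 largest decreases between populations among calls with 1 sign at all stages, 8 and 8 for trends and 5 and 5 for stages and slope differences. It adds the 3 smallest p where none passed, the 10 most abundant in each population, and list members. On data simulated from the real means and depths, with 60 of 265 microRNAs changed, the population test recovered 20%, 80% and 100% of changes of 1, 2 and 4 on the log2 scale, with 0 false calls among 205. The Endo trend recovered 35%, 85% and 100%, the NoEndo trend 45%, 95% and 100%, and the slope difference 10%, 55% and 100%, with 1, 4 and 1 false calls. At changes of 2, the stage tests recovered 15% at 24 hpf, 45% at 48 hpf, 20% at 72 hpf and 5% at 6 dpf, with 1, 2, 0 and 4 false calls among 205. Each simulation was 1 draw, with 1 spread per microRNA over all libraries. Apart from the simulated changes, no microRNA varied with stage, and increases and decreases were equal in number, unlike in the real data. The rates may therefore not carry over to it.

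Alternatives were DESeq2 size factors, total counts alone, no filter, a 100 CPM filter, the DESeq2 Wald test, limma-voom, each use of the identical file, leaving out each library, a replicate term, no stage term, summed arms, removal of the most abundant microRNA, an omnibus test and stage rank. In addition, 4 settings were added after the data were seen, leaving out both libraries with the outermost TMM factors, leaving out both 24 hpf libraries, thinning all libraries to the smallest, and leaving out 1 of the 2 entries with identical counts (miR-133a-5p and miR-133a-2-5p). Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.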

Results

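Small RNA was sequenced from cells sorted out of dissociated transgenic zebrafish at 24, 48 and 72 hpf (hours post fertilization) and at 6 dpf (days post fertilization). The series is about how microRNAs in endothelial cells, the cells that line blood vessels, differ over 4 stages of development. By title, 6 libraries belong to an Endo and 6 to a NoEndo population. The source, tissue, stain and sorting labels of the NoEndo libraries also read endothelial and GFP, so the groups rest on the titles alone, and which cells the NoEndo sort held is not given in the sources used here. Replicate 1 of Endo and replicate 1 of NoEndo at 72 hpf hold identical values, so neither was used in a comparison. This left 5 libraries of each population, with 2 of each at 48 hpf and 1 of each at 24 hpf, 72 hpf and 6 dpf. Nothing in the labels says that replicates came from separate clutches, so p-values measure only the spread between these samples, which may be technical.

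In the Endo libraries, reads on mature microRNAs numbered 324476 at 24 hpf, 1068864 and 743938 in replicates 1 and 2 at 48 hpf, 996643 at 72 hpf and 250084 at 6 dpf. In the NoEndo libraries they numbered 643870 at 24 hpf, 657337 and 2311070 in replicates 1 and 2 at 48 hpf, 5028382 at 72 hpf and 1739921 at 6 dpf. A count of 0 allows a level of up to 0.602 CPM (the depth-scaled count, here worth 3 counts) in the deepest library and 12 CPM in the shallowest before TMM scaling, counting error only. Mature microRNA reads were 13.5% ± 4.29 of the larger library total in Endo and 28.6% ± 8.82 in NoEndo (SD, n = 5). The file headers do not define that total. The share was lower in Endo in an exact two-sided permutation test (p = 0.0159, adjusted p = 0.0317 over 6 library measures). The divisions, here and for the other library measures, ignored the matching of the populations by stage. Endo libraries listed 273 ± 26.5 microRNAs and NoEndo libraries 306.6 ± 14.1 (exact permutation p = 0.00794, the smallest that 5 against 5 allows, adjusted p = 0.0317). That number grows with depth. After thinning to 249950 counts per library it was 260.0 ± 20.1 and 287 ± 12.4 (exact permutation p = 0.0159).

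miR-92a-3p, a member of the miR-17-92 family, was the most abundant microRNA on average in both populations, at 16.0% ± 4.24 of counts in Endo and 14.9% ± 5.95 in NoEndo (SD, n = 5 here and in this paragraph). By library, miR-430b-3p led in Endo at 24 hpf, miR-125b-5p in Endo at 72 hpf and 6 dpf, and miR-205-5p in NoEndo replicate 1 at 48 hpf and at 72 hpf, and miR-92a-3p in the others. It was followed in Endo by miR-125b-5p, with 10.1% ± 7.34 against 8.11% ± 5.24 in NoEndo, and by miR-222a-3p, with 7.58% ± 2.58 against 3.504% ± 0.976. miR-205-5p, a microRNA of epithelia, held 11.4% ± 5.68 of counts in NoEndo and 1.17% ± 0.818 in Endo. The skin microRNA miR-203b-3p held 4.38% ± 2.95 in NoEndo and 0.330% ± 0.195 in Endo. In the other direction, miR-150, known from lymphocytes, held 4.10% ± 2.26 in Endo and 0.0397% ± 0.0165 in NoEndo. miR-221-3p, miR-23b and miR-23a-3p, which are linked to vascular growth, held 4.68% ± 1.85, 3.45% ± 1.91 and 3.16% ± 1.63 in Endo, against 2.49% ± 0.788, 1.27% ± 0.392 and 1.67% ± 0.359 in NoEndo. miR-430b-3p, of the family that clears maternal transcripts from the early embryo, ranged from 0.0200% to 27.7% over the Endo libraries and from 0.0166% to 18.9% over the NoEndo libraries. The remaining most abundant microRNAs were miR-125a (4.76% ± 3.77 and 2.62% ± 2.18 in Endo and NoEndo), miR-125c-5p (3.96% ± 2.73 and 3.11% ± 2.04), miR-204-5p (1.84% ± 1.14 and 3.66% ± 0.652) and miR-92b-3p (0.765% ± 0.129 and 2.39% ± 0.835).

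The miR-126 family, which endothelial cells express and which vessel integrity depends on, was higher in Endo. miR-126a-3p averaged 31469.5 ± 14097 CPM in Endo and 257 ± 92.03 CPM in NoEndo (SD, n = 5), a 117-fold difference with every Endo library above every NoEndo library (log2 6.87, SE 0.45, adjusted p = 7.67e-08). miR-126b-3p was 120.5-fold higher in Endo (log2 6.91, SE 0.43) at 8464 ± 3993 against 73.1 ± 29.2 CPM, and the shared 5' arm entry of both hairpins was 82.0-fold higher (log2 6.36, SE 0.48). miR-150 was 125.6-fold higher (log2 6.97, SE 0.57, adjusted p = 8.42e-07), at 55417 ± 47673 CPM in Endo and 437 ± 423 CPM in NoEndo. The 6 dpf libraries raise both means of miR-150, with 131084 CPM against 8836 to 66381 in the other Endo libraries and 1174 CPM against 113 to 353 in the other NoEndo libraries. Their TMM factors of 0.468 in Endo and 0.568 in NoEndo enlarge these values. Before TMM scaling, miR-150 ran from 7752 to 61348 CPM in Endo and from 267 to 666 CPM in NoEndo. In the opposite direction, the epithelial microRNAs miR-200b-3p, at 674 ± 287 CPM in Endo and 5718 ± 2988 CPM in NoEndo (log2 -3.04, SE 0.46), and miR-205-5p, at 13573 ± 9157 and 111748 ± 75220 CPM (log2 -3.07, SE 0.53), were lower in Endo.

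Both arms of miR-139 were higher in Endo, miR-139-3p by 4.41 (SE 0.43) and miR-139-5p by 3.11 (SE 0.40) on the log2 scale. At a mean of at least 100 CPM and with 1 sign at all 4 stages, the other microRNAs with the largest increases were let-7e (3.57, SE 0.47), miR-338 (3.36, SE 0.55), the myeloid microRNA miR-223 (3.06, SE 0.47, 3363 ± 2523 CPM in Endo and 373 ± 198.7 in NoEndo, n = 5), miR-187 (2.74, SE 0.41), and the vascular microRNAs miR-221-5p (1.70, SE 0.36) and miR-222a-3p (1.498, SE 0.36). The largest decreases within these limits, on the same log2 scale, were in the skin microRNAs miR-203b-5p (-3.61, SE 0.58), miR-203a-3p (-3.55, SE 0.69) and miR-203b-3p (-3.43, SE 0.67), and in miR-429b (-3.47, SE 0.41), miR-200c-3p (-3.32, SE 0.48) and miR-429a (-3.29, SE 0.51) of the epithelial miR-200 family. Further decreases were in miR-725-3p (-3.27, SE 0.46), in miR-184 of the lens (-3.03, SE 0.35, 1375 ± 922 and 13223 ± 13397 CPM, with 36335 in NoEndo at 6 dpf and 2829 to 12233 in the other NoEndo libraries), in miR-375 of pancreatic islets (-2.57, SE 0.38) and in miR-217 of the exocrine pancreas (-2.45, SE 0.46). The TMM factor of NoEndo at 6 dpf, 0.568, enlarges the value of miR-184 there.

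In Zv9 coordinates, miR-126a-3p lies on chromosome 8 at 12065968-12065988, miR-126b-3p on chromosome 11 at 38496011-38496032, miR-150 on chromosome 3 at 32708295-32708316, miR-139-5p on chromosome 15 at 47153835-47153852 and miR-139-3p at 47153872-47153894 of the same chromosome. miR-205-5p lies on chromosome 23 at 33503962-33503983, as do miR-200b-3p at 24358961-24358982 and miR-429a at 24360748-24360769. In the gene table of the assembly GRCz12tu, which served for names and for the genes that hold these hairpins, the hairpin of miR-126b lies within the span of egfl7, an endothelial gene, that of miR-139 within pde2a, and those of miR-200b and miR-429a within ttll10.

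Of 265 microRNAs tested with edgeR and a term for stage, 111 passed at an adjusted p under 0.05, of which 38 were higher and 73 lower in Endo, and 95 of the 111 had 1 sign at all 4 stages. Scaled by total counts alone, 19 were higher and 89 lower, and the median difference of all microRNAs moved by -0.47 on the log2 scale. The count was 65 without NoEndo replicate 2 at 72 hpf, 70 without Endo replicate 2 at 72 hpf, 43 with no term for stage, and 40, 27 and 113 with the identical file kept under both titles, as NoEndo and as Endo. Keeping it as NoEndo ended the calls of miR-139-3p, miR-338, miR-223, miR-187, miR-221-5p, miR-222a-3p, miR-203a-3p, miR-203b-3p and miR-725-3p, and turned the direction of 0 of the 111. Across microRNAs, that file correlated more with every Endo library used than with any NoEndo library used, which argues against its NoEndo title.

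**Figure D1:**
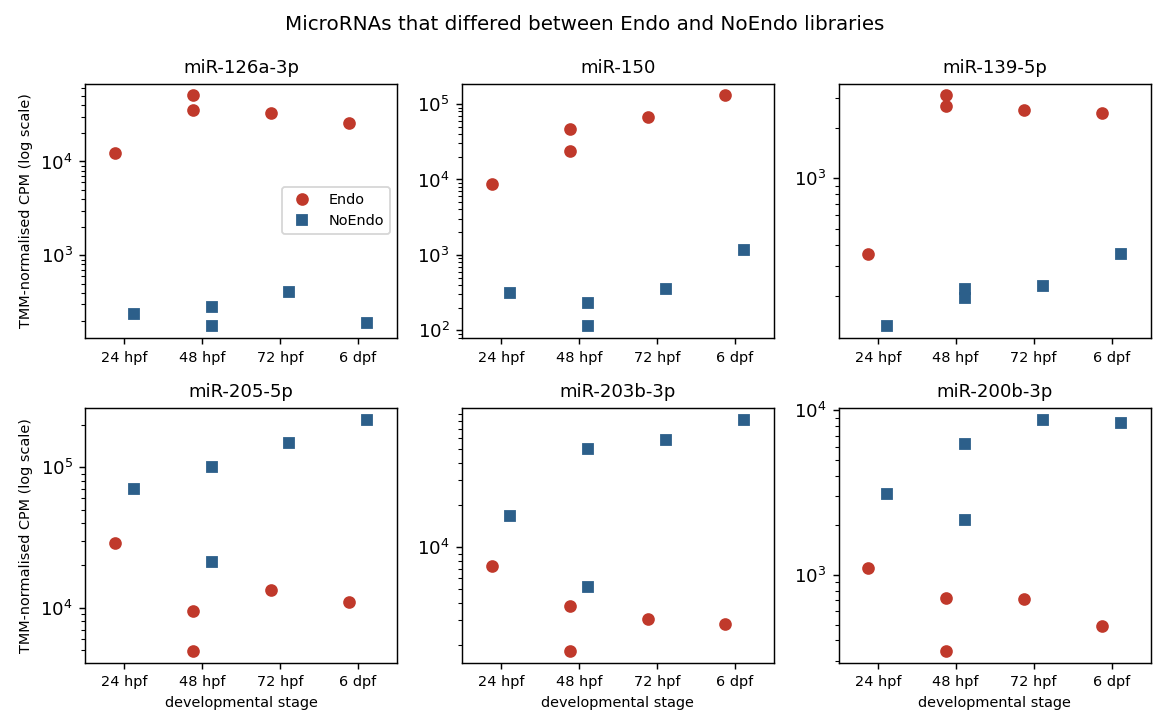
Normalised level (TMM-scaled CPM, log scale) of 6 microRNAs in the 5 Endo (circles) and 5 NoEndo (squares) libraries by developmental stage, 1 point per library. At each stage the Endo points lie above the NoEndo points for miR-126a-3p, miR-150 and miR-139-5p, and below them for miR-205-5p, miR-203b-3p and miR-200b-3p.

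Of the lists fixed before the data were examined, 3 were higher in Endo as groups. All 3 tested members of the miR-126 list were higher, over all microRNAs and adjusted over the list alone, with a median log2 difference of 6.87 (camera adjusted p = 9.05e-11, and adjusted p = 0.0991 with an estimated correlation). In the leukocyte list, 3 of 6 tested members were higher, and 4 adjusted over the list alone, with a median of 1.62 (camera adjusted p = 0.00169, and adjusted p = 0.173 with an estimated correlation). Its called members were miR-150, miR-223 and miR-142a-3p (2.19, SE 0.66), the last a microRNA of blood cells, while miR-155 (1.04, SE 0.41), miR-146b (0.81, SE 0.47) and miR-146a (0.78, SE 0.58) did not pass over all microRNAs. miR-451, the 1 tested microRNA of the erythroid list, did not pass (-0.67, SE 0.36). Among the 36 tested members of the list of other vascular microRNAs, 16 were higher and 2 lower, with the same counts adjusted over the list alone. The median of that list was 0.87 (camera adjusted p = 0.00152, and adjusted p = 0.355 with an estimated correlation). Its fry adjusted p was 0.0158, but 0.0512, 0.0510 and 0.0508 without Endo replicate 2 at 48 hpf, Endo at 6 dpf and NoEndo at 6 dpf. Besides both arms of miR-139, miR-221 and miR-222a, with miR-222b at 3.71 (SE 0.63), its higher members included miR-23b (1.63, SE 0.45), miR-24 (1.36, SE 0.36) and miR-27b-3p (1.19, SE 0.33), which share clusters, and the hypoxia microRNA miR-210-3p (1.18, SE 0.31). At 24 hpf, miR-23b and miR-24 were not higher in Endo. There, miR-23b was at 5330 TMM-scaled CPM in Endo and 8014 in NoEndo, and miR-24 at 3161 and 3830. The 2 lower members were miR-10d-3p (-1.74, SE 0.52) and miR-27e (-1.40, SE 0.50). Scaled by total counts, the median of the vascular list was 0.37, and the calls of miR-142a-3p, miR-24, both arms of miR-27b and of miR-210, miR-23a-5p, miR-23a-3-5p, miR-222a-5p and miR-100-5p ended.

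MicroRNAs of several other tissues were lower in Endo, the population with the lower share of mature microRNA reads. All 12 tested members of the epithelial list were lower, also adjusted over the list alone, with a median log2 difference of -3.22 (camera adjusted p = 1.41e-06, and adjusted p = 0.355 with an estimated correlation). All 5 tested members of the list of sensory epithelia were lower, over all microRNAs and adjusted over the list alone, with a median of -2.44 (camera adjusted p = 0.00921, and adjusted p = 0.314 with an estimated correlation). The 5 are arms of miR-182, miR-183 and miR-96, which lie within 10 kb of each other on 1 strand, so they are not independent. They included miR-183-5p (-3.65, SE 0.57), miR-182-5p (-3.61, SE 0.92) and miR-96-5p (-2.44, SE 0.71), which hair cells and photoreceptors express. In the 5 Endo libraries, miR-183-5p had 1 to 3 counts and miR-182-5p 0 to 2, so the sizes of their differences are poorly set. The more abundant 3p arms were at -2.21 (SE 0.39) for miR-183 and -2.26 (SE 0.51) for miR-182. In the neural list, 20 of 29 tested members were lower, and 21 adjusted over the list alone, with a median of -1.87 (camera adjusted p = 1.50e-05, and adjusted p = 0.173 with an estimated correlation). Examples were miR-124-5p (-2.18, SE 0.43) of neurons, miR-9-3p (-1.92, SE 0.34) of neural progenitors, and miR-34b (-5.41, SE 0.94) and miR-34c-5p (-3.71, SE 0.59), which multiciliated cells also express. miR-34b had 1 count in Endo replicate 1 at 48 hpf and 0 in the other Endo libraries, so the size of its difference is poorly set. miR-128-3p of the brain did not pass (-0.11, SE 0.27).

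Some members passed in lists that did not as groups in camera, which ranks a list against the other microRNAs. The fry test asks whether the members themselves shift in 1 direction. All 4 gut and liver members were lower, also adjusted over the list alone, among them miR-122 of hepatocytes (-2.33, SE 0.53) and miR-192 of the gut (-1.84, SE 0.53), with a camera adjusted p of 0.0971 for the list, and 0.0105 or 0.0104 without Endo or NoEndo at 24 hpf. Its fry adjusted p was 0.0491, but 0.0632 to 0.138 without any 1 library of the later stages. The decrease lay at those later stages. At 24 hpf, with 1 library each, no member was lower in Endo. There, miR-192 was at 338 TMM-scaled CPM in Endo and 231 in NoEndo, miR-122 at 24.6 and 10.3, miR-194a at 49.2 and 31.0, and miR-194b at 7.03 and 6.89. Of the 4 tested endocrine and pancreas microRNAs, 2 were lower, and 4 adjusted over the list alone (camera adjusted p = 0.0520, fry adjusted p = 0.00924). Its camera adjusted p was 0.0369, 0.0308, 0.0371 and 0.0148 without Endo at 24 hpf, Endo replicate 2 at 48 hpf, NoEndo at 24 hpf and NoEndo replicate 1 at 48 hpf. Of the 4 eye microRNAs, 2 were lower, with the same count adjusted over the list alone (camera adjusted p = 0.179, fry adjusted p = 0.00924). miR-204-5p did not pass (-0.70, SE 0.50). Of 10 tested muscle microRNAs, 3 were lower, and 2 adjusted over the list alone, namely miR-499-5p (-1.64, SE 0.34), miR-133c-3p (-1.19, SE 0.37) and, over all microRNAs, miR-1 (-0.95, SE 0.36), with a camera adjusted p of 0.196. Its fry adjusted p was 0.0508, but 0.00235 with total counts and 0.00920 without NoEndo replicate 2 at 48 hpf. Among the 10, the entries of miR-133a-5p and miR-133a-2-5p hold the same counts in every library, and with 1 of them left out 3 of 9 were lower, with a fry adjusted p of 0.0453. Of 9 mesenchyme microRNAs, 3 were lower, also adjusted over the list alone, namely miR-140-3p of cartilage (-1.13, SE 0.33), miR-199-5p (-1.05, SE 0.35) and miR-143 of smooth muscle (-0.996, SE 0.31), with a camera adjusted p of 0.226. Its fry adjusted p was 0.0138, but 0.0510 or 0.0508 without Endo or NoEndo at 6 dpf.

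Broadly expressed families did not pass as groups in camera. No member of the 7 tested in the miR-430 list passed (median 0.42, camera adjusted p = 0.418, fry adjusted p = 0.250). Of 21 tested members of the miR-17-92 list, miR-20b-5p (1.05, SE 0.32) and miR-18c (0.97, SE 0.33) were higher and miR-92b-3p (-1.12, SE 0.33) and miR-92b-5p (-1.40, SE 0.52) lower, with 0 adjusted over the list alone (median 0.03, camera adjusted p = 0.555, fry adjusted p = 0.717). In the let-7 list, let-7e, let-7d-5p (1.31, SE 0.33) and let-7c-5p (0.94, SE 0.34) were higher among 10 tested, also adjusted over the list alone (median 0.40, camera adjusted p = 0.179). Its fry adjusted p was 0.0491, but 0.498 with total counts and 0.0519 to 0.0968 without any 1 library. Of 13 tested microRNAs encoded in Hox clusters, only miR-10d-3p passed, and 0 adjusted over the list alone (median -0.34, camera adjusted p = 0.726). Its fry adjusted p was 0.228, but 0.00255 with total counts and 0.0187 without NoEndo replicate 2 at 48 hpf. Scaled by total counts, the medians of the miR-430, miR-17-92 and let-7 lists turned negative, to -0.02, -0.46 and -0.06, and the calls of miR-20b-5p, miR-18c, let-7d-5p and let-7c-5p ended.

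**Figure D2:**
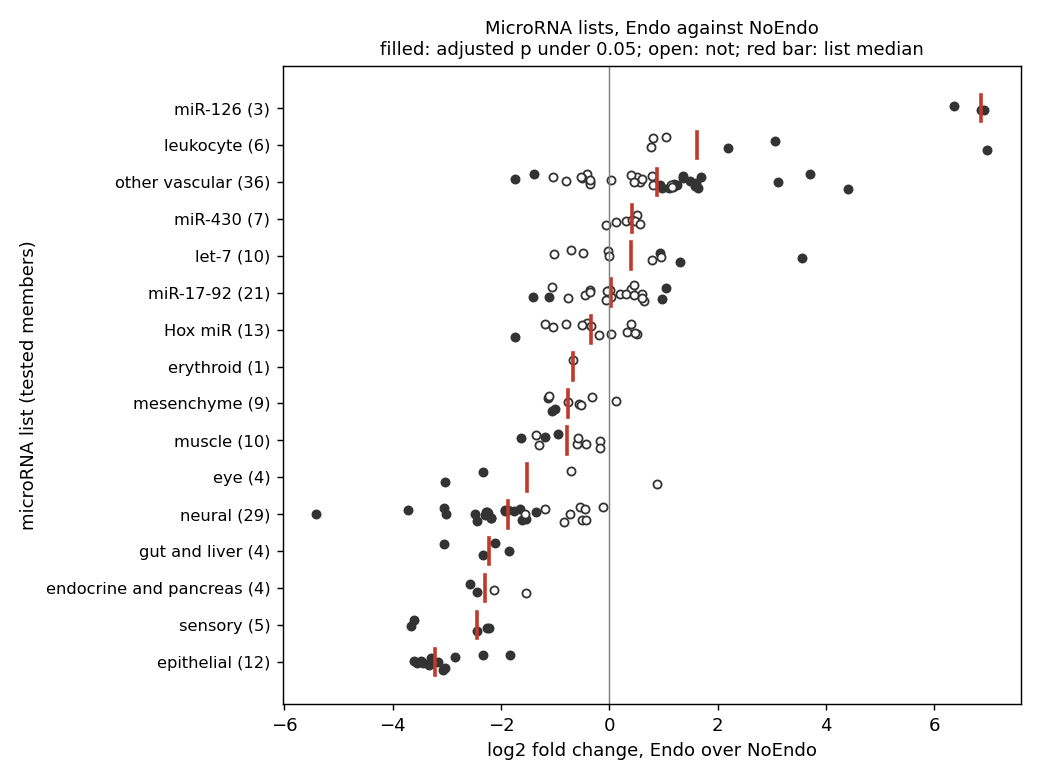
Log2 fold change of Endo over NoEndo for each tested member of 16 microRNA lists (filled points passed at an adjusted p under 0.05, open points did not, bars are list medians). The medians run from 6.87 for miR-126 to -3.22 for the epithelial list, and those of miR-430, miR-17-92 and let-7 turn negative when scaled by total counts.

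The populations were also compared within each stage, to see at which ages the difference could be measured. The spread came from the 48 hpf pairs alone, and lone libraries of the other stages were assumed to vary like them. miR-126b-3p was higher in Endo at 24 hpf (log2 6.36, SE 0.87, adjusted p = 0.0322), 48 hpf (7.21, SE 0.63), 72 hpf (6.07, SE 0.85) and 6 dpf (7.79, SE 0.93). miR-126a-3p was likewise higher, by 5.71 (SE 0.88), 7.57 (SE 0.67), 6.35 (SE 0.90) and 7.09 (SE 0.94) at these stages, and the shared 5' arm entry from 48 hpf on, by 6.75 (SE 0.79), 5.34 (SE 1.04) and 6.94 (SE 1.14). miR-150 was higher at 48 hpf (7.70, SE 0.80), 72 hpf (7.56, SE 1.12) and 6 dpf (6.80, SE 1.08), and was at 4.81 (SE 0.99) without passing at 24 hpf (adjusted p = 0.103). At 48 hpf miR-139-3p was higher (4.75, SE 0.79), and at 72 hpf let-7e (3.72, SE 0.71). Lower in Endo at 48 hpf were the epithelial miR-203b-5p (-3.82, SE 0.93), miR-429b (-3.53, SE 0.72), miR-429a (-3.05, SE 0.63) and miR-200c-3p (-2.97, SE 0.70), and miR-725-3p (-3.40, SE 0.76). At 72 hpf, miR-429a (-4.72, SE 0.97), miR-192 (-3.73, SE 0.78) and the hepatocyte microRNA miR-122 (-3.65, SE 0.73) were lower, and at 6 dpf miR-375 (-3.80, SE 0.71). DESeq2 size factors ended every call at 24 and 72 hpf, all but those of miR-126a-3p and miR-126b-3p at 6 dpf, and, as did limma-voom, those of miR-203b-5p and miR-200c-3p at 48 hpf. Without NoEndo replicate 1 at 48 hpf, the call of miR-203b-5p ended at -2.13 and miR-200c-3p was at -1.91. Total counts ended every call at 24 hpf, all but that of miR-150 at 72 hpf, and all but those of miR-126a-3p and miR-150 at 6 dpf. Thinning ended the calls of the 5' arm entry at 72 hpf and 6 dpf and of miR-429a and miR-192 at 72 hpf, and limma-voom that of miR-375, which also ended without NoEndo replicate 2 at 72 hpf.

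In edgeR with 1 mean per population and stage, 2 microRNAs passed at 24 hpf (2 higher, 0 lower), 28 at 48 hpf (13 higher, 15 lower), 10 at 72 hpf (7 higher, 3 lower) and 5 at 6 dpf (4 higher, 1 lower), with 29, 96, 61 and 64 at an unadjusted p under 0.05. On simulated data the 6 dpf test gave 4 false calls, so single calls there are weakly supported. That was 1 draw in which lone libraries varied like the others, so it does not measure the error if they vary more. Differences between stages are tested as slopes in the comparison of trends. Without either Endo library of 48 hpf, the counts at 24 hpf, 72 hpf and 6 dpf were 0 and that at 48 hpf 3 or 4, and without either NoEndo library of 48 hpf they were 8, 33 or 31, 35 or 36 and, at 48 hpf, 45 or 37. They were 0 at all 4 stages with the identical file kept as NoEndo, 8, 66, 35 and 28 with DESeq2, 17 at 72 hpf and 11 at 6 dpf without Endo at 24 hpf, and 16 at 72 hpf without NoEndo at 24 hpf.

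With age, miR-430 microRNAs fell in both populations. miR-430b-3p fell in Endo from 315252 CPM at 24 hpf to 427 CPM at 6 dpf, a slope of -3.68 (SE 0.29) on the log2 scale per doubling of age, and in NoEndo from 208812 to 293 CPM (-3.59, SE 0.29). miR-430c-3p (-4.00, SE 0.41 in Endo and -3.99, SE 0.37 in NoEndo) and miR-430a-3p (-3.21, SE 0.55 and -3.16, SE 0.50) fell likewise, and miR-430c-3p had no count in Endo at 6 dpf, which allows up to 25.6 TMM-scaled CPM. miR-145-5p, a microRNA of smooth muscle, rose in Endo from 148 to 10267 CPM (2.40, SE 0.30) and in NoEndo from 326 to 16043 CPM (2.17, SE 0.26). miR-122 of the liver rose by 2.52 (SE 0.49) in Endo and 4.05 (SE 0.68) in NoEndo, and miR-125a by 1.79 (SE 0.24) and 1.99 (SE 0.24).

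Further rises in Endo were in miR-29a (1.89, SE 0.35), miR-125b-5p (1.53, SE 0.30), miR-125c-5p (1.46, SE 0.31) and miR-187 (1.35, SE 0.34). Further falls in Endo were in miR-10a-3p (-1.77, SE 0.42) and miR-196b (-1.41, SE 0.29), both from Hox clusters, and in miR-430a-5p (-1.71, SE 0.32). Of 24 other settings, 13 ended the Endo call of miR-187 and 10 that of miR-10a-3p, total counts, no filter and limma-voom among them for each. Total counts also ended the Endo calls of miR-122 and miR-29a, whose slope was 0.74 without Endo at 6 dpf. In NoEndo, miR-462 (2.22, SE 0.43) and miR-731 (1.94, SE 0.50), which share a genomic cluster, rose with miR-129-3p (2.14, SE 0.30) and miR-129-1-3p (1.74, SE 0.29) of the nervous system and with miR-187 (1.68, SE 0.33). The falls in NoEndo included miR-19a-3p (-1.66, SE 0.47) and miR-19b-3p (-1.51, SE 0.37) of the miR-17-92 clusters, miR-133c-3p of muscle (-1.49, SE 0.39), miR-196b (-1.43, SE 0.26) and miR-430b-5p (-1.36, SE 0.37). Without NoEndo at 6 dpf none of these NoEndo calls stood, and the slopes of miR-462, miR-129-3p, miR-129-1-3p and miR-187 were 0.50, 1.09, 0.81 and 0.81. Total counts ended those of miR-129-1-3p, miR-187, miR-19a-3p, miR-19b-3p, miR-133c-3p and miR-430b-5p, and without NoEndo at 24 hpf the slope of miR-133c-3p was -0.72.

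By list, 4 of 7 tested miR-430 members fell in Endo and 6 in NoEndo, and 7 in each adjusted over the list alone, with median slopes of -2.20 and -2.47 that stayed negative under each of 3 scalings. Of 21 tested members of the miR-17-92 list, 7 fell in NoEndo, and 11 adjusted over the list alone, while 0 passed in Endo by either count (median slopes -1.06 and -0.57). The let-7 family, known for its rise in differentiating tissue, had median slopes of 1.43 in Endo and 1.20 in NoEndo, with 0 and 1 of 10 tested members passing over all microRNAs and adjusted over the list alone. Scaled by total counts, the median slope of all microRNAs was -0.45 in Endo and -0.32 in NoEndo, and those of let-7 were 0.90 and 0.61.

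In edgeR, 15 microRNAs changed with age in Endo (8 up, 7 down) and 40 in NoEndo (22 up, 18 down). Of these, 12 passed in both populations, all with the same sign, where chance gives 2.26 (Fisher's exact test, p = 9.45e-09, across microRNAs, which are not independent). Both slopes came from 1 model with a shared spread per microRNA. The sets of calls are thus not independent either, as the chance number assumes. The slopes differed between Endo and NoEndo for 0 microRNAs, with 12 at an unadjusted p under 0.05, 0 by limma-voom and 1 by DESeq2. That 1 was miR-724 (difference -1.58, SE 0.41, adjusted p = 0.0272), which in edgeR had a difference of -1.59 (SE 0.37, adjusted p = 0.385), ahead of miR-146a (-1.60, SE 0.60) and miR-194a (-2.13, SE 0.83). The count in Endo was 5 without Endo at 24 hpf, 3 without Endo at 6 dpf (miR-430b-3p, miR-430c-3p and miR-145-5p), 31 without NoEndo at 24 hpf, 27 without NoEndo at 6 dpf and 57 by DESeq2. The count in NoEndo was 3 without NoEndo at 6 dpf (miR-430b-3p, miR-430c-3p and miR-122), which also turned the slope of miR-731 to -0.32, 20 when scaled by total counts and 74 by DESeq2.

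**Figure D3:**
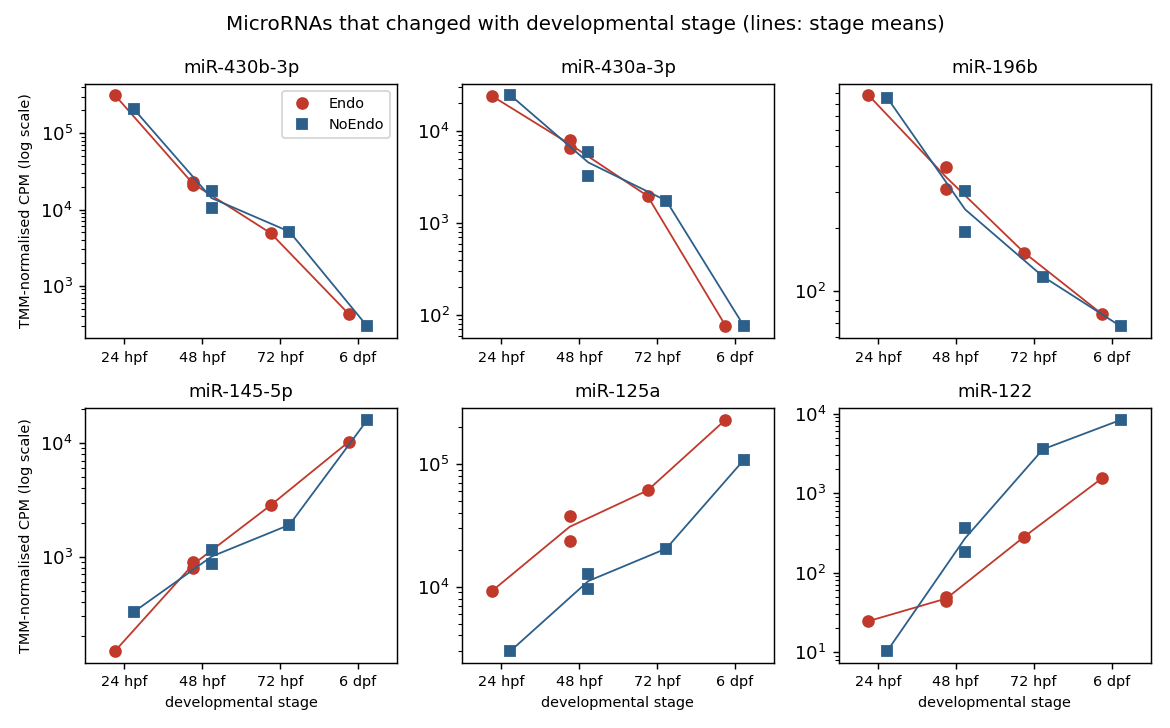
Normalised level (TMM-scaled CPM, log scale) of 6 microRNAs against developmental stage, 1 point per library, with lines through stage means of Endo (circles) and NoEndo (squares). miR-430b-3p fell in Endo from 315252 to 427 CPM and in NoEndo from 208812 to 293 CPM, while miR-145-5p, miR-125a and miR-122 rose in both.

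Reads antisense to mature microRNAs were rare in both populations. They made up 12.3 ± 8.30 ppm of sense and antisense counts in Endo and 1.73 ± 1.06 in NoEndo (SD, n = 5), higher in Endo in an exact two-sided permutation test (p = 0.0159, adjusted p = 0.0317 over 6 library measures). The libraries ranged from 2.39 to 20.004 ppm in Endo and from 0.0698 to 2.92 in NoEndo, and the share rests on 0.0455 to 12 adjusted counts per library. Restricted to entries with at least 2 counts, the antisense share was 8.39 ± 6.23 and 1.21 ± 1.23 ppm (exact permutation p = 0.0397, adjusted p = 0.0595). Without any 1 of the NoEndo libraries, the exact permutation p of the antisense share rose to between 0.0556 and 0.0635.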

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

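The tests of scaling, of miR-142a-3p against miR-150 and of uniform carry-over were chosen after their results were seen, thinning after the other results but before its own, and the other tests before.

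The file that stands under both the Endo and the NoEndo title as replicate 1 at 72 hpf was used in no comparison and holds miR-126a-3p at 13545 CPM, above the NoEndo libraries (107 to 502 CPM) and inside the range of the Endo libraries (10804 to 64324 CPM, before TMM scaling). It holds miR-150 at 34181 CPM (7752 to 61348 in Endo, 267 to 666 in NoEndo), miR-205-5p at 5807 (5153 to 25423 and 49895 to 185676) and miR-200b-3p at 308 (228 to 966 and 2819 to 10892). Its miR-203b-3p, at 1093 CPM, lies below both the Endo (1316 to 6435) and the NoEndo libraries (12365 to 72798). Across microRNAs, which are not independent replicates, its log2 CPM correlated with those of the 72 hpf replicate 2 libraries at r = 0.964 for Endo and 0.806 for NoEndo. Over all Endo libraries used, r ran from 0.874 to 0.964, and over all NoEndo libraries used from 0.770 to 0.836. These values argue against the NoEndo title for this file. Which sample the file came from was not tested, and no group was assigned to it in the main comparisons.

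Of 100 splits of the 10 libraries into 5 and 5, 1 gave as many as 111 differing microRNAs, namely the real one, and the highest other gave 20. Each other split mixed Endo and NoEndo libraries, which widens the spread within its groups and holds its calls down. Stages were not kept balanced either, so the splits cannot exclude chance for that count. For the slope difference, with a real count of 0, all 100 splits gave as many and the highest other gave 28. Any split gives at least 0, so this comparison decides nothing about chance. Splits that call many microRNAs point to some structure of the samples, and which one was not tested.

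More microRNAs were called lower than higher in Endo, with 34.2% of 111 calls higher. The scaling between libraries moved this share, and its highest value over 3 scalings was 38.3%, so none of the 3 gave an even division. After thinning every library to 249950 counts, 36.6% of 101 calls were higher, with 96 of them called at full depth too and 0 changes of sign, which argues against unequal depth as the whole source. A scaling by an outside reference, such as spiked-in RNA, is not analysed here, so a difference in total microRNA per cell may still shift the share, as total counts alone did, to 17.6%. A biological difference between the populations stays open and untested.

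miR-150, miR-223 and miR-142a-3p, all known from leukocytes, were higher in Endo, and a candidate explanation is leukocytes in the Endo sort, whose gate was GFP. The excess of miR-142a-3p was at most 0.704% of that of miR-150 over the 5 Endo libraries, and the ratio of miR-223 to miR-142a-3p ranged 21.6-fold, from 8.56 at 6 dpf to 185 in replicate 1 at 48 hpf. miR-142a-3p had only 16 to 161 counts per Endo library, and the make-up of zebrafish leukocytes was not measured, so leukocytes and expression in the sorted endothelial cells themselves cannot be told apart. miR-150 stood at 8836 CPM at 24 hpf and 131084 CPM at 6 dpf in Endo, and miR-223 at 1512 and 1171 CPM. These values are scaled by TMM factors of 0.878 at 24 hpf and 0.468 at 6 dpf.

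MicroRNAs of other tissues were present in Endo libraries at unequal ratios to NoEndo. The median ratio was 10.7% for the epithelial list, 18.5% for sensory, 21.5% for gut and liver, 27.3% for neural, 58.6% for muscle and 59.0% for mesenchyme. A uniform carry-over of NoEndo cells would give 1 ratio, while the muscle median lay 2.45 above the epithelial median on the log2 scale, a pair picked after the medians were seen, and 2.27 above it with 1 of 2 muscle entries of identical counts left out. Over all 8 lists of other tissues, with no pair picked, the members differed by list (permutation p = 1e-05, the smallest the draws can give, with members taken as independent), which argues against it as the whole source. An unequal carry-over of cell types, a difference in handling between the sorts, and expression in endothelial cells may each add to these levels, and none of them was tested.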

How the results depend on the processing

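The settings that left out both libraries with the outermost TMM factors or both 24 hpf libraries, thinned all libraries, or left out 1 of the 2 identical miR-133a 5' arm entries, were chosen after the data were seen. Named microRNAs kept direction and call in 631 of 648 alternatives for Endo against NoEndo, 366 of 495 at single stages, 255 of 311 for the Endo trend and 344 of 383 for the NoEndo trend. They were picked as the largest calls in the same data, so these numbers do not describe the other calls. The 1 change of direction was the NoEndo trend of miR-731, -0.32 without NoEndo replicate 1 at 6 dpf (adjusted p = 0.729), in a range of -0.32 to 3.53 without single libraries. The causes were not tested, except that fewer libraries or microRNAs were used where some were left out. Low counts limit rare microRNAs most in Endo at 6 dpf, where 3 counts are 12 CPM.

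Endo against NoEndo gave 40 calls with the identical file kept under both titles, 27 as NoEndo, 113 as Endo, 43 with no stage term, and 65 to 120 without single libraries. It gave 75 without the libraries with the outermost TMM factors, 117 without 24 hpf, 101 after thinning and 111 without 1 of the 2 identical entries, with 0 changes of sign among the 111 calls under any of these.

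At 24 hpf, 48 hpf, 72 hpf and 6 dpf, in this order, a 100 CPM filter gave 4, 50, 25 and 30 calls, DESeq2 8, 66, 35 and 28, and replicate number as a term 20, 134, 90 and 86. That number pairs only the 48 hpf libraries, whose replicate difference correlated across populations (r = 0.656 across microRNAs), and the labels do not say what it stands for. With it as a term, the spread rested on only 1 contrast between the 48 hpf pairs, less than in the main stage test. The identical file kept under both titles, or as NoEndo, gave 0 at each of the 4. At 24 hpf, 72 hpf and 6 dpf, DESeq2 size factors gave 0, 0 and 2, total counts 0, 1 and 2, and the identical file kept as Endo 4, 51 and 17. limma-voom gave 17 at 72 hpf. Without single libraries the counts ran from 0 to 8, 3 to 45, 0 to 33 and 0 to 36 over the 4 stages, and a stage left without an Endo or NoEndo library gave none.

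For the Endo trend, DESeq2 size factors gave 27, the 100 CPM filter 25, DESeq2 57, the identical file as Endo 29, replicate number as a term 23, the omnibus test 32, the outermost TMM factors left out 3, both 24 hpf libraries left out 40, thinning 25, and single libraries left out 3 to 31. For the NoEndo trend, total counts gave 20, DESeq2 74, both 24 hpf libraries left out 70, and single libraries left out 3 to 47. The slope difference gave 1 with DESeq2 and 0 in the other settings, including each library left out.

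Of the lists, 6 passed camera and 0 did with an estimated correlation, 6 without 1 of the 2 identical entries, 7 with replicate number as a block, which added endocrine and pancreas (camera adjusted p = 0.0191), and without single libraries 6 to 8. In fry, the same block ended the calls of the gut and liver list (fry adjusted p = 0.0712) and the let-7 list (fry adjusted p = 0.0581). The antisense share differed by 8.60 to 13.0 ppm without single libraries, with 10.5, 10.1, 10.7, 10.8 and 10.6 where a NoEndo library was left out and the exact permutation p no longer passed.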

Other observations

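The tests of arms and of neighbours were set before their results were seen, and the microRNAs outside the lists and the pairs that stood apart were chosen after their values were seen.

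Outside the lists, the miR-135 family was lower in Endo, with miR-135c at -1.98 (SE 0.39), miR-135a at -2.10 (SE 0.51), miR-135b-5p at -1.80 (SE 0.44) and miR-135b-3p at -2.12 (SE 0.62) on the log2 scale. miR-148 (-1.50, SE 0.38), miR-455-3p (-1.05, SE 0.33) and both arms of miR-2188 (-1.07, SE 0.31 for 5p and -3.35, SE 0.77 for 3p) were lower too. miR-2188-3p had 3 and 2 counts in Endo replicates 1 and 2 at 48 hpf and 0 in the other Endo libraries, so the size of its difference is poorly set. Higher in Endo were miR-125a (1.44, SE 0.29), miR-735-5p (1.47, SE 0.35), miR-22a-5p (1.14, SE 0.35), miR-130a (1.04, SE 0.32), miR-99 (0.89, SE 0.27) and miR-30c-3p (1.79, SE 0.53), the last not at all 4 stages. Scaling by total counts ended the calls of miR-22a-5p, miR-130a and miR-99.

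The 5p and 3p arms of 1 microRNA differed alike between Endo and NoEndo. Over 60 microRNAs with a 5p and a 3p entry of the same name, the log2 differences of the arms correlated at r = 0.894 and rho = 0.905 (permutation p = 1e-05 for each, the smallest the draws can give). Without the 2 farthest microRNAs, r was 0.895. Counts were summed over genomic copies, so some of the 60, such as miR-9 and miR-430a, join several hairpins. These microRNAs are not independent replicates. Both arms passed in 22 of them, in opposite directions in 0, and 1 arm alone passed in 10.

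MicroRNAs within 10 kb of each other on 1 strand also differed alike. Over 95 pairs of 92 microRNAs from different hairpins, the median absolute difference between neighbours was 0.36 on the log2 scale, against 1.49 after shuffling (permutation p = 1e-04, the smallest the draws can give). Pairs that stood apart were let-7a and let-7e, at 0.80 and 3.57, and miR-24 and miR-27e, at 1.36 and -1.40. Reads shared between let-7 members, or between miR-27 members, were not tested as a source of these gaps. Many pairs overlap within the same cluster, so they are not independent. Some join near-identical microRNAs, such as miR-430 members, and shared reads were not tested as a source of their likeness.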
